A study of Mus musculus with 18 samples.

How the data were processed

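RNA of the hippocampus was sequenced from 18 male C57BL/6J mice, 6 each on chow (Control), on a high-fat diet with fructose water (HFFD), and on that regimen with high-dose phlorizin (HFFD+HPH). Per the labels, total RNA was extracted with Trizol, fragmented and reverse-transcribed into cDNA libraries for an Illumina NovaSeq instrument. The labels describe separate mice, so that the spread between libraries holds the variation between animals.

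The authors deposited 1 table of raw counts per gene, whole numbers with no normalization, for all 18 libraries. Per the submitters' processing notes the reads were trimmed with Trimmomatic 0.38, and HISAT2 and featureCounts were named with the builds GRCm38.p6 and mm10. Versions of the latter tools, the annotation release, the strand setting, the treatment of reads with several positions and the source of the features without an Ensembl identifier are not given in the sources used here. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with close copies can lose or share reads. Values of both kinds of gene are uncertain, and the text marks only some of them. Nor can counts tell a gene's own change from a change in the cells or tissue that a library holds.

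The table held 55244 features, of which 54446 had Ensembl identifiers and 798 had other identifiers that name no known gene. The latter took 0.298% to 0.487% of the counts of a library. A symbol was found for 54409 of the 54446 by identifier. Coordinates were taken from GENCODE release M21 on GRCm38 by identifier. Total counts ranged from 20772977 to 27257841 per library, and 30084 to 35836 features had at least 1 count. No pair of the 45 pairs of libraries within a group was within sampling noise (chi-square over degrees of freedom 11.4 to 181).

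Differential expression was tested in R 4.3.3 with edgeR 4.0.16 by its quasi-likelihood F test, on the counts as deposited, with TMM factors, the filterByExpr filter and 1 fit with a mean per group over all 18 libraries. This left 20384 genes, which took 99.7% to 99.9% of each library's counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all genes tested. CPM values use the TMM-scaled library sizes, SE is the log2 fold change over the square root of its F statistic, and log2 CPM used a prior count of 2. The share of variance between groups was taken by PERMANOVA (vegan 2.7.1) on Euclidean distances of log2 CPM.

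A set of 52 gene lists (31 of functions, 2 of RNA quality and 19 of cell types and regions) was fixed, with the design, the alternatives and the rule for named genes, before the data were examined. Each list with at least 3 tested members was tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, with fry, and by an exact permutation of its mean score. For each list, called members were also counted when adjusted over the list alone. The rule for named genes took, per comparison, the 10 genes that rose and the 10 that fell with the smallest p among called genes with a mean of at least 1 CPM, 4 members per called list and at most 2 per other list, 10 genes called in opposite directions in both comparisons, and always Slc5a1, Slc5a2, Slc2a1 and Bdnf. The text names part of these, and says where a gene outside the rule was chosen after its values were seen. After the data were seen, 3 lists of cerebellar, brainstem and spinal cord, and telencephalic genes were added, with their mean scores as covariates in an alternative fit. Some single genes of these and other lists, among them the marker by which the doubted libraries were chosen, are not reported here.

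The comparisons made were HFFD with Control, HFFD+HPH with HFFD, and HFFD+HPH with Control. The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 1 CPM in 6 libraries, a 1.5-fold minimum, only the 12 libraries compared, the replicate number as a block, surrogate variables (sva 3.50.0), a choroid plexus score, the regional scores, and leaving out libraries.

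The edgeR fit was tested on simulated counts with the means and library sizes of the 20384 genes and 200 genes changed by known folds. For HFFD against Control it recovered 31.3%, 71.6% and 87.9% of the genes changed 1.5-fold, 2-fold and 4-fold, with 6 false calls. For HFFD+HPH against HFFD it recovered 40.3%, 65.7% and 97.0% with 10 false calls, and for HFFD+HPH against Control 32.8%, 55.2% and 87.9% with 3 false calls. The simulation gave every group the same spread per gene. In the data, chi-square over degrees of freedom reached 181 within HFFD+HPH, 77.4 within HFFD and 64.7 within Control. The shares recovered and the false calls therefore need not hold for the deposited counts. Simulated groups with no effect that shared libraries gave a correlation of comparisons that share the HFFD group, with each gene drawn on its own.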

Results

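Hippocampal RNA was sequenced from 18 male C57BL/6J mice, an inbred laboratory strain, in 3 groups of 6 that were kept on their regimen for 14 weeks. The Control group had chow. The HFFD group had a diet with 45% of its energy from fat, and 10% fructose in its drinking water. The HFFD+HPH group had that diet and drink together with phlorizin at 20 mg per kg per day, the high dose in the labels. Phlorizin is a plant glucoside that blocks the sodium-glucose cotransporters Slc5a1 and Slc5a2. Each library came from 1 mouse and held between 20772977 reads counted to genes (Control 6) and 27257841 (HFFD 4), so that a level of 1 CPM, the count scaled to the TMM-adjusted library total, stood for 20.4 to 27.9 reads. Levels are given in CPM as mean ± SD with n = 6 mice per group, and fold changes on the log2 scale ± SE.

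Genes that mark brain regions outside the hippocampus set the libraries apart. Gabra6 and Cbln3, which are expressed by cerebellar granule cells, stood at 0.886 ± 0.135 and 3.01 ± 0.768 CPM in Control, at 287 ± 115 and 689 ± 262 CPM in HFFD, and at 205 ± 213 and 470 ± 464 CPM in HFFD+HPH (n = 6 each). Slc6a5, the glycine transporter of brainstem and spinal cord neurons, stood at 0.955 ± 0.536, 182 ± 72.4 and 88.9 ± 135 CPM in the same order. The telencephalon is the part of the brain that holds the hippocampus. Slc6a5 was chosen after its values were seen, as were 3 marker lists of cerebellar, brainstem and spinal cord, and telencephalic genes.

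Between HFFD and Control, 16 of 16 cerebellar genes and 15 of 15 brainstem and spinal cord genes rose, with median log2 fold changes of 5.17 and 5.11, and 9 of 10 telencephalic genes fell, with a median of -3.44. Camera adjusted p was 2.00e-13, 3.48e-07 and 2.29e-05 for the 3 lists, and adjusted p = 0.123 for each with an estimated correlation. Between HFFD+HPH and HFFD, 5 of the 10 telencephalic genes rose (median 2.42), while edgeR called 0 of the 16 cerebellar genes (median -0.59; 0 at an unadjusted p under 0.05, 0 by DESeq2, 15 by limma-voom) and 0 of the 15 brainstem genes (median -1.03; 2 at an unadjusted p under 0.05, 0 by DESeq2, 13 by limma-voom). Camera adjusted p was 2.25e-05 for the telencephalic and cerebellar lists and 2.30e-07 for the brainstem list, and adjusted p = 0.185, 0.243 and 0.185 with an estimated correlation. Between HFFD+HPH and Control, 16 cerebellar and 11 of 15 brainstem genes rose, with medians of 4.20 and 4.02 (limma-voom called 16 and 0). For the telencephalic list that median was -0.91, and edgeR called 0 of its 10 genes (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom). The mean score of each list separated HFFD from Control by an exact two-sided permutation test (p = 0.00216 for each list, 0.00487 after Benjamini-Hochberg adjustment over 9 tests). A p of 0.00216 is the smallest this test can give with 6 libraries per group. Since the lists were chosen after these libraries were seen, the camera and permutation p-values describe the libraries and are no independent support. For HFFD+HPH against HFFD the exact permutation p was 0.121 (cerebellum), 0.0455 (brainstem) and 0.0519 (telencephalon), and 0.121, 0.0584 and 0.0584 after adjustment. Against Control it was 0.00216, 0.0390 and 0.0303 for HFFD+HPH, and 0.00487, 0.0584 and 0.0545 after adjustment.

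**Figure D1:**
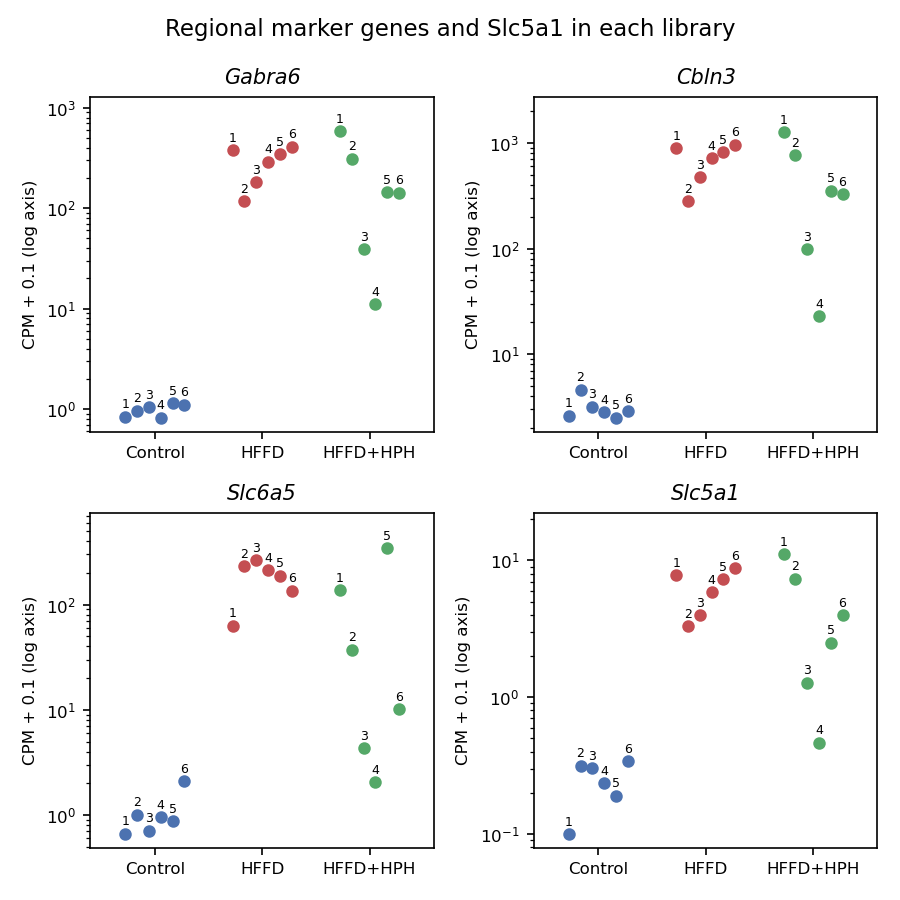
Level of 4 genes in each library, as CPM plus 0.1 on a log axis, for Control, HFFD and HFFD+HPH; each point is 1 mouse and the digit beside it is the replicate number. Gabra6 lies between 118 and 409 CPM in HFFD and at most 1.05 CPM in Control, and ranges from 11 to 583 CPM in HFFD+HPH.

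Over all 20384 genes tested, group membership accounted for 45.9% of the variance between libraries (permutation test, p = 9e-05). The share was 60.5% for HFFD against Control, 23.4% for HFFD+HPH against HFFD and 26.3% for HFFD+HPH against Control, with exact permutation p of 0.00216, 0.0281 and 0.00433 for the 3 comparisons in that order. The first principal component, along which libraries differed most, held 56.0% of the variance. It correlated with the telencephalic score at r = -0.895. On it HFFD+HPH 3, 4 and 6 lay at -51.5, -53.2 and -28.9, and Control at -73.5 to -51.8. HFFD+HPH 1, 2 and 5 lay at 60.3, 24.1 and 65.5, and HFFD at 24.2 to 87.97.

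The first comparison sets libraries of mice on the high-fat, high-fructose diet against those of chow-fed mice. Their telencephalic scores did not overlap (-3.12 to -0.561 in HFFD, 1.19 to 2.065 in Control). A difference in tissue can therefore not be told apart from one by diet. Genes of excitatory synapses, neuropeptides and activity-dependent transcription were lower in HFFD as lists, and genes of myelin, astrocytes, interferon response and blood were higher, each list with an adjusted p of 0.686 or 0.690 with an estimated correlation. Egr1, an activity-induced transcription factor, fell from 278 ± 57.6 to 38.7 ± 5.06 CPM, and the inhibitory neuropeptide Npy fell from 39.0 ± 11.4 to 5.12 ± 1.11 CPM (n = 6 each). Homer1, a scaffold of the postsynaptic density, fell from 195 ± 28 to 49.1 ± 11.3 CPM. The myelin lipid enzyme Ugt8a rose from 31.7 ± 10.6 to 89.0 ± 20.9 CPM, and the interferon-induced gene Ifit3 rose from 5.13 ± 0.797 to 14.5 ± 6.51 CPM. In total edgeR called 9493 of 20384 genes (46.6%), of which 4920 rose and 4573 fell, and 3393 of these calls exceeded a 2-fold change.

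Among the genes with the smallest p, the cerebellar markers led those that rose. Gabra6 (ENSMUSG00000020428, chromosome 11, 42306437 to 42321072 in GRCm38, protein coding) rose by 8.33 ± 0.84, and Cbln3 (chromosome 14, 55878913 to 55884392) by 7.83 ± 0.80, with an edgeR adjusted p of 3.48e-05 for each. Pcp2, a Purkinje cell gene, rose from 0.569 ± 0.0982 to 88.0 ± 33.5 CPM, and the junction gene Cgn from 8.85 ± 1.29 to 22.1 ± 1.44 CPM (edgeR adjusted p = 7.61e-05). Net1, a guanine nucleotide exchange factor for RhoA (chromosome 13, 3882018 to 3918220, overlapping Gm47813 on the same strand), fell by 1.19 ± 0.10, from 37.4 ± 5.52 to 16.3 ± 2.06 CPM (edgeR adjusted p = 1.15e-05). The small GTPase gene Arl4d fell from 24.1 ± 6.27 to 7.67 ± 0.729 CPM and the matricellular gene Ccn2 from 26.6 ± 3.43 to 6.15 ± 1.03 CPM. Mertk, a receptor kinase of phagocytic cells, fell from 54.1 ± 4.36 to 27.0 ± 3.68 CPM (edgeR adjusted p = 7.61e-05).

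Synaptic lists moved down together. Of 26 genes for glutamate receptors and the postsynaptic scaffold 22 fell, 2 rose and 2 were not called (22 fell and 2 rose when adjusted over the list alone; median -0.84, camera adjusted p = 1.36e-06). Dlg4, the scaffold PSD-95, fell from 751 ± 76.4 to 369 ± 36.4 CPM. Of 20 genes of synaptic vesicle release 13 fell, with 13 falling and 1 rising when adjusted over the list alone (median -0.40, camera adjusted p = 0.000143), and Syn1, a vesicle phosphoprotein, fell from 538 ± 42.1 to 268 ± 24.2 CPM. Of 15 GABA receptor genes 7 fell by either adjustment (median -0.28, camera adjusted p = 0.0144), with Gabra4 falling from 125 ± 6.65 to 31.9 ± 9.96 CPM. Among 14 neuropeptide genes 9 fell by either adjustment (median -1.63, camera adjusted p = 0.00206), Npy by 2.93 ± 0.37 (edgeR adjusted p = 0.000115) and Cck from 163 ± 27.0 to 25.0 ± 9.78 CPM. Of 18 immediate early genes 14 fell by either adjustment (median -2.13, camera adjusted p = 4.91e-06). Egr1 fell by 2.84 ± 0.35, Fosl2 from 62.0 ± 19.2 to 13 ± 3.07 CPM, and Fosb from 20.7 ± 6.10 to 2.81 ± 0.639 CPM. With an estimated correlation each of these 5 lists had an adjusted p = 0.686. The cerebellar list rose by a median of 5.17 and the telencephalic list fell by 3.44 in the same libraries.

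Marker lists of cell types and regions were called as well. All 6 genes of the CA1 pyramidal list fell (median -2.01, camera adjusted p = 0.00233). Of 5 CA3 genes 3 fell, and 4 when adjusted over the list alone (median -1.56, camera adjusted p = 0.0144). Of 8 striatal genes 6 fell (7 when adjusted over the list alone; median -1.79, camera adjusted p = 0.00576). Of 10 neocortical genes 8 fell and 1 rose (9 fell and 1 rose when adjusted over the list alone; median -1.36, camera adjusted p = 0.00357). Of 12 oligodendrocyte genes 9 rose by either adjustment (median 0.89, camera adjusted p = 0.00422), among them Ugt8a and the myelin glycoprotein Mag, from 132 ± 51.3 to 289 ± 68.3 CPM. Of 11 astrocyte genes 6 rose and 1 fell (8 and 1 when adjusted over the list alone; median 0.39, camera adjusted p = 0.0247), with the water channel Aqp4 rising from 96.1 ± 22.6 to 286 ± 33.7 CPM and S100b from 82.8 ± 6.99 to 310 ± 32.8 CPM. Of 14 microglial genes 12 fell by either adjustment (median -0.73, camera adjusted p = 0.000482), the receptor gene Csf1r from 79.7 ± 7.33 to 47.1 ± 9.41 CPM and Cx3cr1 from 41.9 ± 1.91 to 24.1 ± 5.07 CPM. With an estimated correlation each of these 7 lists had an adjusted p = 0.686 or 0.690. In the same libraries brainstem and spinal cord genes rose by a median of 5.11.

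The immune, clock and steroid lists were called in this comparison too. Of 16 interferon-response genes 12 rose, 14 when adjusted over the list alone (median 0.80, camera adjusted p = 0.000675). Ifit3 (chromosome 19, 34583531 to 34588731) had an edgeR adjusted p of 0.000174, and the regulator Irf7 rose from 1.19 ± 0.365 to 3.52 ± 1.75 CPM. Of 11 antigen presentation genes 7 rose, 9 when adjusted over the list alone (median 0.66, camera adjusted p = 0.0135), with the class I gene H2-D1 rising from 38.7 ± 6.14 to 104 ± 16.5 CPM. All 6 blood genes rose by either adjustment (median 1.40, camera adjusted p = 0.00770), the beta-globin gene Hbb-bs from 46.0 ± 9.58 to 142 ± 66.0 CPM. Ifit3, H2-D1 and Hbb-bs have close copies in the genome, and how reads were shared among copies is uncertain. Of 12 glucocorticoid-response genes 7 fell and 1 rose by either adjustment (median -0.61, camera adjusted p = 0.0135), and of 16 clock genes 9 fell and 3 rose by either adjustment (median -0.36, camera adjusted p = 0.0247). Fkbp5, a chaperone of the glucocorticoid receptor and a target of it, fell from 47.6 ± 7.78 to 18.2 ± 4.56 CPM (edgeR adjusted p = 0.000135), and the clock gene Per1 from 140 ± 26.5 to 63.5 ± 11.8 CPM (edgeR adjusted p = 0.000138). The kinase gene Sgk1 fell from 134 ± 61.4 to 53.6 ± 6.31 CPM. With an estimated correlation the adjusted p was 0.686 for interferon, glucocorticoid and blood genes and 0.690 for antigen presentation and clock genes.

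**Figure D2:**
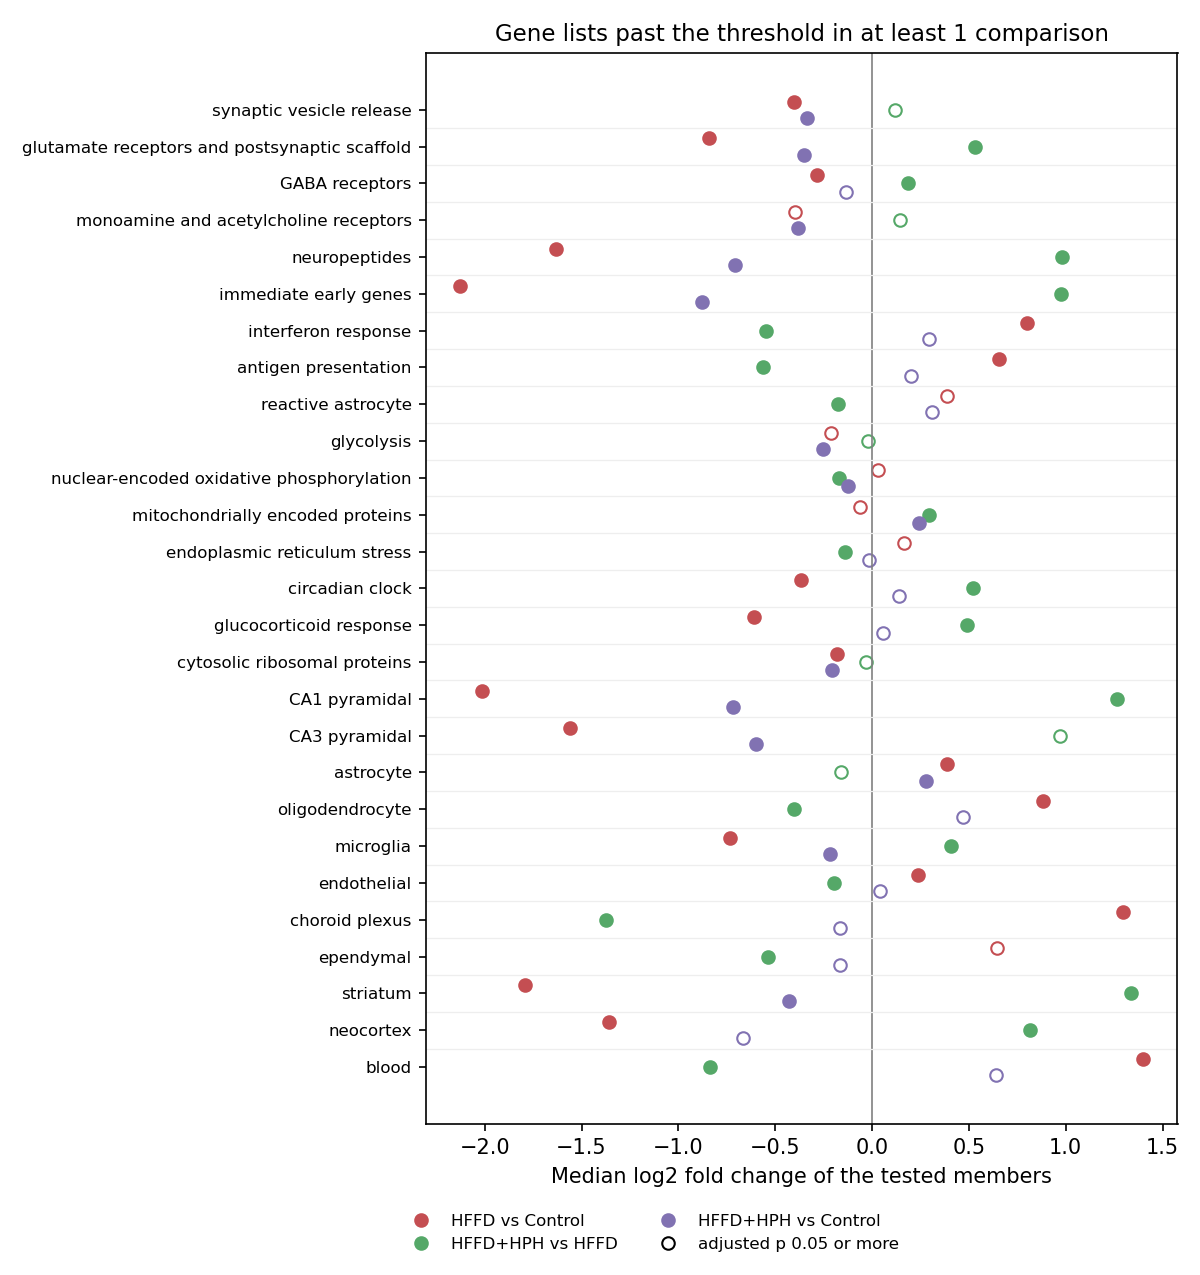
Median log2 fold change (horizontal axis) of the 27 gene lists that passed the camera threshold in at least 1 comparison, with 1 colour per comparison and open circles where the adjusted p was 0.05 or more. Glutamate receptor genes lie at -0.84 for HFFD against Control, at 0.53 for HFFD+HPH against HFFD and at -0.35 for HFFD+HPH against Control.

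Camera called 20 of 52 lists in this comparison, 7 up and 13 down, and 0 of 52 with an estimated correlation. With scores of the 3 regional lists as covariates, an alternative chosen after the data were seen, edgeR called 12 genes, and with 4 surrogate variables 1681. With those 3 scores the estimates for Syn1, Dlg4, Gabra4, Npy, Cck, H2-D1, S100b, Aqp4, Csf1r and Cx3cr1 took the other sign.

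The comparison of HFFD+HPH with HFFD sets mice given phlorizin on the high-fat, high-fructose diet against mice on that diet alone. Of 12 glucocorticoid-response genes 6, and of 16 clock genes 11, were higher with phlorizin (adjusted p = 0.0172 and 0.329 with an estimated correlation). Fkbp5 rose from 18.2 ± 4.56 to 48.0 ± 12.7 CPM, Sgk1 from 53.6 ± 6.31 to 162 ± 19.0 CPM, and Zbtb16, a steroid-induced zinc finger gene, from 19.9 ± 6.76 to 79.6 ± 16.3 CPM (n = 6 each). Ciart, a repressor within the clock, rose from 11.4 ± 1.10 to 24.2 ± 2.28 CPM. Cldn5, the main claudin of the blood-brain barrier, fell from 39.5 ± 4.58 to 19.1 ± 2.78 CPM. In total edgeR called 1363 genes (6.69%), of which 1082 rose and 281 fell, and 562 of these exceeded a 2-fold change. Only the 12 libraries compared gave 68, the replicate number as a block 225, and limma-voom 7751.

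Of 12 glucocorticoid-response genes 6 rose and 6 were not called (6 rose when adjusted over the list alone; median 0.49, camera adjusted p = 8.90e-07, and adjusted p = 0.0172 with an estimated correlation). Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903) rose by 1.59 ± 0.21, Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) by 1.40 ± 0.18, and Zbtb16 (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222) by 2.00 ± 0.25, with an edgeR adjusted p of 0.000692, 0.000848 and 0.000530. Klf9, a steroid-responsive transcription factor, rose from 138 ± 20.3 to 235 ± 38.7 CPM (edgeR adjusted p = 0.00365). Of 16 clock genes 11 rose and 5 were not called (12 rose when adjusted over the list alone; median 0.52, camera adjusted p = 1.17e-08, and adjusted p = 0.329 with an estimated correlation). Ciart (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251) rose by 1.08 ± 0.10 (edgeR adjusted p = 1.30e-05) and Dbp (chromosome 7, 45705088 to 45710203), an output transcription factor of the clock, by 1.10 ± 0.14, from 19.6 ± 1.24 to 42.1 ± 8.99 CPM. Both overlap a gene on the other strand, C920021L13Rik and Sphk2, and since no strand setting is known their reads cannot be told apart. Bhlhe40 rose from 64.9 ± 4.16 to 115 ± 28.2 CPM and Tef from 299 ± 24.5 to 418 ± 51.1 CPM. Telencephalic genes rose by a median of 2.42 in the same libraries.

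Other genes with the smallest p were Net1, which rose by 1.29 ± 0.10 from 16.3 ± 2.06 to 39.9 ± 3.73 CPM (edgeR adjusted p = 6.07e-06), and Mertk (chromosome 2, 128698956 to 128802894), which rose from 27.0 ± 3.68 to 61.3 ± 10.9 CPM (edgeR adjusted p = 3.22e-05). Hif3a (chromosome 7, 17031507 to 17062427), a hypoxia-inducible factor subunit, stood at 13.3 ± 2.91 CPM in Control, 8.29 ± 3.31 in HFFD and 33.0 ± 4.72 in HFFD+HPH, a rise of 1.99 ± 0.21 over HFFD (edgeR adjusted p = 7.20e-05). Arl4d rose from 7.67 ± 0.729 to 18.6 ± 2.52 CPM and the kinase gene Map3k6 from 2.93 ± 0.778 to 8.41 ± 1.45 CPM. Of the 11 endothelial genes 3 fell and 8 were not called (4 fell when adjusted over the list alone; median -0.19, camera adjusted p = 0.00110, and adjusted p = 0.555 with an estimated correlation). Kdr, the VEGF receptor of endothelial cells (chromosome 5, 75932827 to 75978458), fell from 21.7 ± 3.58 to 13.4 ± 1.16 CPM (edgeR adjusted p = 0.00188). Cldn5 (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262) fell by 1.05 ± 0.10 (edgeR adjusted p = 3.22e-05), and the chemokine gene Cxcl12 fell from 72.1 ± 6.99 to 49.5 ± 6.18 CPM. With the 3 regional scores as covariates the endothelial list had a camera adjusted p of 0.415, while Kdr kept its fold change of -0.69 at an edgeR adjusted p of 0.0760.

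Several lists that were lower in HFFD than in Control were higher in HFFD+HPH than in HFFD. The HFFD+HPH libraries were split in this. The mean score of the CA1 list was 1.09, 0.999 and 0.896 in HFFD+HPH 3, 4 and 6. It was -0.99, 0.302 and -1.51 in HFFD+HPH 1, 2 and 5. That score ran from -1.78 to -0.446 in HFFD and from 0.921 to 1.26 in Control. The glutamate receptor score of HFFD+HPH 5 lay below that of every HFFD library. Of 26 glutamate receptor and scaffold genes 10 rose, 16 when adjusted over the list alone (median 0.53, camera adjusted p = 3.96e-06), with Homer1 rising from 49.1 ± 11.3 to 152 ± 75.4 CPM. Of 18 immediate early genes 8 rose and 1 fell (9 and 1 when adjusted over the list alone; median 0.98, camera adjusted p = 0.00249), with Egr1 rising from 38.7 ± 5.06 to 151 ± 81.5 CPM (edgeR adjusted p = 0.00811). Of 14 neuropeptide genes 4 rose, 7 when adjusted over the list alone (median 0.98, camera adjusted p = 0.00572), with Npy rising to 18.8 ± 11.6 CPM. Of 6 CA1 genes 3 rose, 4 when adjusted over the list alone (median 1.26, camera adjusted p = 0.00212). Telencephalic genes rose by a median of 2.42 in the same libraries, and these 4 lists each had an adjusted p = 0.555 with an estimated correlation. That p was also 0.555 for the microglial list, of whose 14 genes 2 rose, 6 when adjusted over the list alone (median 0.41, camera adjusted p = 0.00157), and for the blood list, of whose 6 genes 1 fell, 5 when adjusted over the list alone (median -0.84, camera adjusted p = 0.00445).

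Of 16 interferon-response genes 3 fell between HFFD+HPH and HFFD, 11 when adjusted over the list alone (median -0.55, camera adjusted p = 0.000112), Ifit3 from 14.5 ± 6.51 to 8.04 ± 1.40 CPM (edgeR adjusted p = 0.0348) and Irf9 from 19.5 ± 4.62 to 13.3 ± 1.64 CPM (edgeR adjusted p = 0.0242). Of 18 endoplasmic reticulum stress genes 4 fell, 6 when adjusted over the list alone (median -0.14, camera adjusted p = 0.000823), the chaperone gene Hspa5 from 251 ± 17.4 to 212 ± 11.1 CPM and Creld2 from 15.9 ± 1.17 to 12.5 ± 1.28 CPM. With an estimated correlation both lists had an adjusted p = 0.555, and with surrogate variables the interferon list was no longer called. The calls of these 4 genes were each lost when certain single libraries were left out. Of 13 mitochondrially encoded protein genes edgeR called 0 (8 at an unadjusted p under 0.05, 3 by DESeq2, 10 by limma-voom, 3 rising when adjusted over the list alone), with a median of 0.30 and a camera adjusted p of 0.000422. Of 29 nuclear-encoded oxidative phosphorylation genes edgeR called 0 (9 at an unadjusted p under 0.05, 1 by DESeq2, 12 by limma-voom), with a median of -0.17 and a camera adjusted p of 0.000112. Both had an adjusted p = 0.555 with an estimated correlation.

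**Figure D3:**
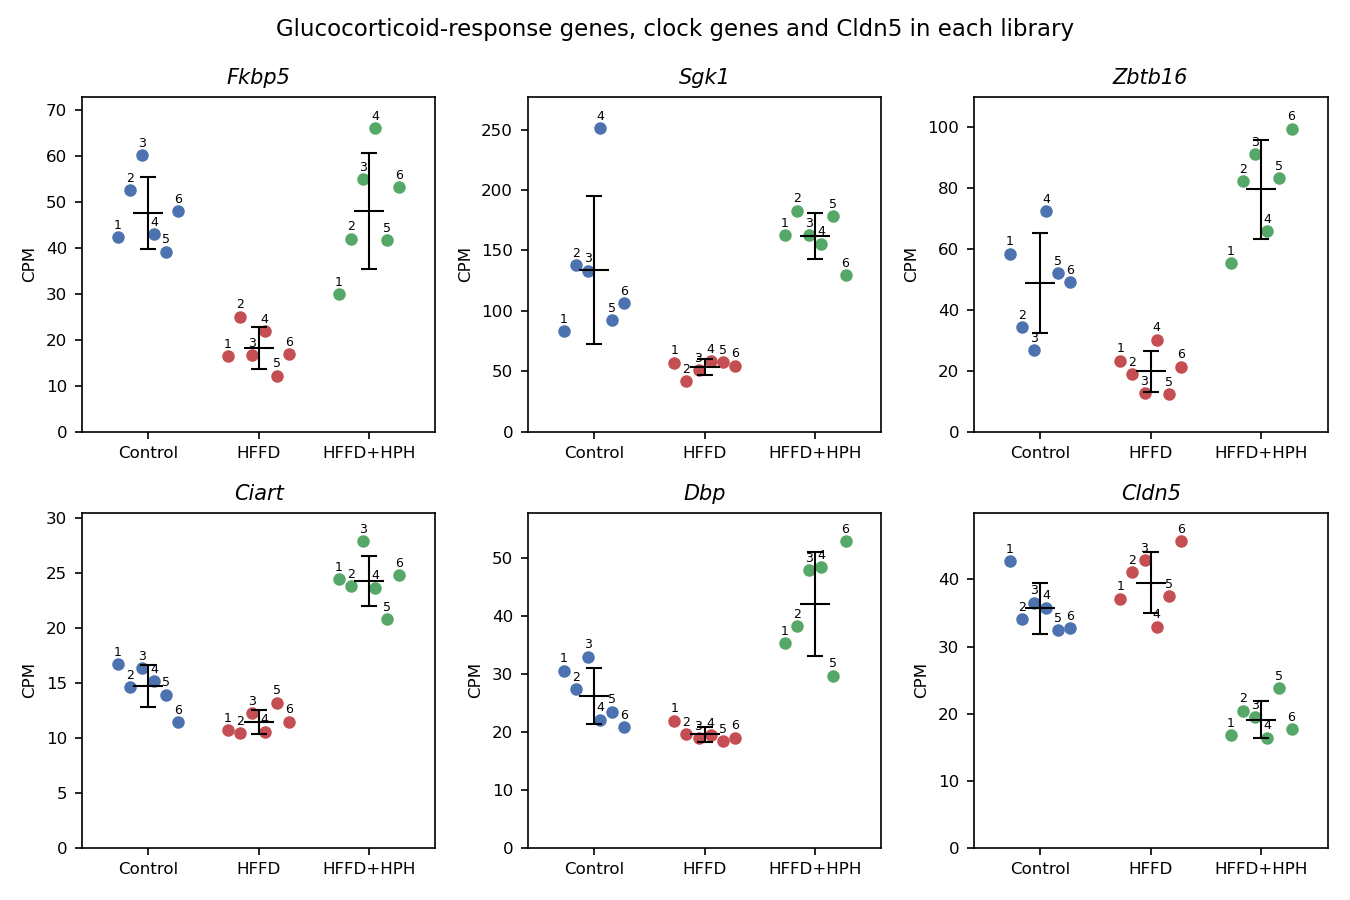
Level of 6 genes in CPM (linear axis) in each library of Control, HFFD and HFFD+HPH; points are single mice with their replicate number, and black marks with bars give mean ± SD (n = 6). Sgk1 averages 53.6 CPM in HFFD and 162 CPM in HFFD+HPH, and Cldn5 averages 39.5 and 19.1 CPM.

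Camera called 21 of 52 lists between HFFD+HPH and HFFD, 11 up and 10 down, and with an estimated correlation 1, the glucocorticoid list. With the 3 regional scores as covariates edgeR called 24 genes, 23 of them among the 1363, and without HFFD+HPH 3, 4 and 6, which were left out after the data were seen and had the 3 lowest cerebellar scores of their group, 22 genes, all among the 1363. The 19 genes called in all 3 fits included Net1, Ciart, Mertk, Hif3a, Arl4d, Map3k6, Dbp, Zbtb16, Sgk1, Fkbp5, Cldn5 and Cxcl12. Leaving out 1 library at a time gave between 185 genes (without HFFD+HPH 3) and 4362 (without HFFD+HPH 5).

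Log2 fold changes between HFFD+HPH and HFFD ran against those between HFFD and Control. Telencephalic genes also fell and then rose (medians -3.44 and 2.42). For these genes as a set, tissue therefore cannot be told apart from diet and phlorizin. Of the 1363 genes called between HFFD+HPH and HFFD, 1270 were also called between HFFD and Control, and all 1270 moved in opposite directions, 1030 lower and then higher and 240 higher and then lower. That count ranged from 173 (without HFFD+HPH 3) to 3827 (without HFFD+HPH 5) with 1 library left out, and was 56 with only the 12 libraries of each comparison and 208 with the replicate number as a block. Independent lists of these sizes would share 243 and 67.8 genes. Shared HFFD libraries can raise opposite calls above that without any reversal, so these numbers are no test of the 1270. Net1 stood at 37.4 ± 5.52, 16.3 ± 2.06 and 39.9 ± 3.73 CPM in Control, HFFD and HFFD+HPH, and Mertk at 54.1 ± 4.36, 27.0 ± 3.68 and 61.3 ± 10.9 CPM (n = 6 each). Across 20384 genes, which are not independent replicates, the log2 fold changes of both comparisons had r = -0.824 (rho = -0.803) and a covariance of -0.419. Both comparisons use the HFFD libraries. Unchanged groups simulated against shared libraries gave a mean r of -0.497 over 10 simulations and a covariance of -0.0386. The simulations drew each gene on its own, while in the data 1 component held 56.0% of the variance between libraries. An r further from -0.497 can therefore arise between unchanged groups. These simulations called at most 0 genes between HFFD and Control and at most 1 between HFFD+HPH and HFFD. Their 0 opposite calls were thus given in advance and say nothing on the 1270. With the HFFD libraries split between the comparisons, r averaged -0.776 over 20 splits (from -0.852 to -0.633) and the covariance -0.364. These values are from differences of mean log2 CPM, which with all HFFD libraries in both comparisons gave r = -0.879 and a covariance of -0.390. Splitting leaves in place any difference in tissue that all HFFD libraries share. With the 3 regional scores as covariates, edgeR called 0 genes in both comparisons in opposite directions (416 at an unadjusted p under 0.05), and r was -0.534.

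The comparison of HFFD+HPH with Control asks how mice given the diet and phlorizin differed from chow-fed mice. Cerebellar genes were again the leading genes that rose, 6 of 16 clock genes were above Control, and 8 of 18 immediate early and 4 of 20 synaptic vesicle genes were below it. With an estimated correlation both of the latter lists had an adjusted p = 0.826. Gabra6 rose by 7.85 ± 0.83 with an edgeR adjusted p of 0.000240, and Car8, a Purkinje cell gene, from 10.8 ± 1.5 to 496 ± 507 CPM (n = 6 each). Cldn5 fell from 35.7 ± 3.82 to 19.1 ± 2.78 CPM (edgeR adjusted p = 0.000252) and Kdr from 19.2 ± 1.63 to 13.4 ± 1.16 CPM (edgeR adjusted p = 0.00715). Ciart rose from 14.7 ± 1.90 to 24.2 ± 2.28 CPM (edgeR adjusted p = 0.000723), and Nr1d2, a nuclear receptor of the clock, from 120 ± 15.2 to 214 ± 36.1 CPM (edgeR adjusted p = 0.00115). In total edgeR called 2316 genes (11.4%), of which 1628 rose and 688 fell, and 675 of these exceeded a 2-fold change. Leaving out 1 library gave from 647 (without HFFD+HPH 1) to 3925 (without HFFD+HPH 3), and only the 12 libraries compared gave 188.

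Of 18 immediate early genes 8 fell, 15 when adjusted over the list alone (median -0.88, camera adjusted p = 4.05e-07), Fosl2 from 62.0 ± 19.2 to 28 ± 9.23 CPM and Arc, which encodes a synaptic plasticity protein, from 169 ± 84.9 to 56.0 ± 32.1 CPM, a call lost without Control 1, Control 2 or HFFD+HPH 1. Of 20 synaptic vesicle genes 4 fell, 12 when adjusted over the list alone (median -0.34, camera adjusted p = 1.04e-05), with Syp falling from 814 ± 84.1 to 629 ± 76.2 CPM and Syn1 from 538 ± 42.1 to 357 ± 96.5 CPM. Of 15 glycolysis genes 4 fell and 1 rose, 9 and 1 when adjusted over the list alone (median -0.25, camera adjusted p = 0.00161), with the aldolase gene Aldoa falling by 0.37 ± 0.09 (edgeR adjusted p = 0.0194), a call lost without Control 2. Of 33 ribosomal protein genes 1 fell (median -0.21, camera adjusted p = 2.45e-05). Of 11 astrocyte genes 3 rose by either adjustment (median 0.28, camera adjusted p = 0.0424), Aqp4 to 206 ± 91.6 CPM and S100b to 197 ± 120 CPM. With an estimated correlation all 14 lists called had an adjusted p = 0.826. In the same libraries cerebellar genes rose by a median of 4.20.

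Neither steroid nor interferon genes passed as lists in this comparison. The glucocorticoid list had 1 gene that rose, 3 when adjusted over the list alone (median 0.06, camera adjusted p = 0.483), and that gene, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 62.1 ± 11.5 to 116 ± 34.2 CPM (edgeR adjusted p = 0.00591). The clock list had 6 genes that rose (7 rose and 2 fell when adjusted over the list alone; median 0.14, camera adjusted p = 0.0753). Of 16 interferon genes edgeR called 0 (5 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom), with 5 rising when adjusted over the list alone (median 0.30, camera adjusted p = 0.0594). Among single genes, Midn, which encodes a nuclear protein, fell from 68.7 ± 10.1 to 44.2 ± 5.77 CPM. With the 3 regional scores as covariates edgeR called 200 genes, and 35 without HFFD+HPH 1, 2 and 5, the other 3 libraries of that group, left out after the data were seen. With the regional scores the estimates for Syn1, Aqp4 and S100b took the other sign.

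The transporters that phlorizin blocks and the related glucose carrier were reported in each comparison. Slc5a1 (ENSMUSG00000011034, chromosome 5, 33104219 to 33162870, with 5033423K11Rik on the other strand), the intestinal sodium-glucose cotransporter, stood at 0.148 ± 0.0911 CPM in Control, 6.08 ± 2.19 in HFFD and 4.34 ± 4.05 in HFFD+HPH (n = 6 each). It rose by 5.31 ± 0.73 between HFFD and Control (edgeR adjusted p = 0.000135) and by 4.83 ± 0.73 between HFFD+HPH and Control (edgeR adjusted p = 0.00213), and was not called between HFFD+HPH and HFFD (-0.48 ± 0.53, edgeR adjusted p = 0.590). The cerebellar genes rose by medians of 5.17 and 4.20 in the first and second of these. Slc5a2 (chromosome 7, 128265657 to 128272430), the renal cotransporter, had 20, 20 and 24 reads in all over the 6 libraries of Control, HFFD and HFFD+HPH, too few to be tested, and a difference was not detectable at this depth. Slc2a1 (chromosome 4, 119108711 to 119137983), the glucose carrier of the blood-brain barrier, stood at 99.8 ± 11, 108 ± 8.30 and 145 ± 24.1 CPM. It rose in HFFD+HPH against HFFD (0.42 ± 0.10, edgeR adjusted p = 0.0233, a call lost without HFFD 5 or HFFD+HPH 3) and against Control (0.54 ± 0.10, edgeR adjusted p = 0.00618), and was not called between HFFD and Control (0.11 ± 0.10, edgeR adjusted p = 0.361). Bdnf (chromosome 2, 109674700 to 109727007), a neurotrophin, fell from 21.9 ± 2.10 to 15.8 ± 0.827 CPM between HFFD and Control (edgeR adjusted p = 0.00309). It stood at 20.2 ± 4.18 CPM in HFFD+HPH, not called against HFFD (0.36 ± 0.12, edgeR adjusted p = 0.0657) or against Control (-0.12 ± 0.11, edgeR adjusted p = 0.499).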

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

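Of the tests in this part, those of other splits of the libraries and of the slope on the forebrain score were set before their results were seen, and the others were chosen after.

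A sample far from the other 5 of its group, by Dixon's test on log2 CPM, was found for 18 of 186 pairs of a named gene and a group (9.68%), where chance gives about 1 in 20. HFFD+HPH 5 accounts for 6 of them. It was lowest of its group for Per1 (71.5 CPM, others 113 to 137), Klf9 (162 CPM) and Tef (321 CPM), and highest for Ugt8a (114 CPM), Mag (441 CPM) and Plin4 (73.4 CPM). Control 4 was highest for Ugt8a (52.1 CPM) and Tsc22d3 (85.2 CPM) and lowest for Cx3cr1 (38.4 CPM). Single values stood apart for Fosb in HFFD 4 (1.58 CPM), Irf7 in HFFD+HPH 6 (1.64 CPM), Dbp in HFFD 1 (22.0 CPM), Kdr in HFFD 3 (28.7 CPM) and Hspa5 in HFFD+HPH 1 (191 CPM). The same held for Creld2 in HFFD 6 (18.1 CPM), Slc6a5 in Control 6 (2.01 CPM), Fmo2 in Control 5 (2.41 CPM) and C1qc in HFFD+HPH 1 (8.92 CPM).

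The counts of genes were set against 100 of the 462 splits of each pair of groups, the real split included. For HFFD against Control 1 split, the real one, gave as many as 9493 genes, and the highest other gave 5076. For HFFD+HPH against HFFD 4 splits gave 1363 genes or more, with 3582 as the highest other, and for HFFD+HPH against Control 2 splits gave 2316 or more, with 3532 as the highest other. For HFFD against Control no other split drawn reached the real count, which argues against chance there. For both comparisons with HFFD+HPH fewer splits reached the real count than the limit set beforehand. Chance was still not excluded for them, since only part of the splits was drawn and some called more genes than the real one. A split that calls more genes than the real one points to a structure among the libraries other than the group. The split with 3582 calls put HFFD+HPH 1 and 5 with 4 HFFD libraries. For the counts of gene lists chance was not excluded: 12 splits gave 20 lists or more (highest other 24), 8 gave 21 or more (highest other 25) and 36 gave 14 or more (highest other 24).

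The 9493 genes called between HFFD and Control came with cerebellar and brainstem markers far above their Control level. Diet acting on the same tissue in every library is argued against as the whole cause, since Gabra6 spanned 5.72 log2 units among the HFFD+HPH libraries, which shared 1 treatment. A swap of some libraries between Control and HFFD is argued against because 0 Control libraries held Gabra6 above 10 CPM, a limit chosen after these values were seen. So is a single wrong label as the whole cause, since at least 8392 genes were called with any 1 library left out. A candidate explanation is tissue of other brain regions in the libraries: across 9453 called genes, the fold change correlated with the slope on the forebrain score within the HFFD+HPH libraries alone at r = -0.849 (rho = -0.878, from -0.868 to -0.799 with 1 library left out), and 91.9% of genes had opposite signs. Over all genes tested outside the 3 regional lists r was -0.776. The forebrain score rests on the telencephalic list, which was chosen after these libraries were seen. Of the marker genes, 13 of 16 cerebellar, 1 of 15 brainstem and 10 of 10 telencephalic genes had a Control mean of at least 1 CPM, and 1, 1 and 3 also belong to lists fixed earlier. An exchange of all Control and all HFFD libraries would leave the same values and stays open, as does a mix-up with HFFD+HPH libraries. Several samples from outside the series and an effect of the diet beside any difference in tissue stay open. With the 3 regional scores 12 genes were called between HFFD and Control, but each score parted all libraries of the 2 groups, so that this fit excludes no wider effect of the diet.

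The rise of glucocorticoid-response and clock genes between HFFD and HFFD+HPH was opposite in direction to the change of both lists between Control and HFFD. The rise had an adjusted p = 0.0172 for the glucocorticoid list with an estimated correlation. Tissue of other regions as the whole cause is argued against for the glucocorticoid list. With the 3 regional scores it kept 1.32 times its median (0.49 before, 0.65 after, camera adjusted p = 3.63e-13). The clock list kept 0.648 times (0.52 before, 0.34 after, camera adjusted p = 7.53e-10). Without those scores the clock list had an adjusted p = 0.329 with an estimated correlation. HFFD+HPH 5 had the lowest telencephalic score (-3.35). Its clock score of -0.28 lay inside the HFFD range (-0.48 to -0.19), against 0.25 to 0.38 in the rest of its group. Its glucocorticoid score of 0.34 lay above the HFFD range (-0.52 to -0.26). Tissue of other regions therefore stays open for the clock list. A difference in the time of day of collection stays open and cannot be told apart from phlorizin, since no collection time is in the labels. The evening-phase clock genes had a median of 0.70 and the morning-phase genes Arntl, Npas2 and Clock one of -0.05, a difference of 0.755, although Npas2 itself rose by 1.62 (edgeR adjusted p = 0.0379). Phlorizin acting on glucocorticoid signalling, or stress at handling that differed between groups, may also underlie it, and neither was tested.

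The interferon list rose between HFFD and Control and fell between HFFD+HPH and HFFD (adjusted p = 0.686 and 0.555 with an estimated correlation). Tissue of other regions cannot be told apart from diet and phlorizin for either. For the fall, the median kept 0.738 of its size with the 3 regional scores (-0.55 before, -0.40 after, camera adjusted p = 0.00381), but with surrogate variables the call ended (-0.32, camera adjusted p = 0.0691). For the rise the median kept 0.513 with the regional scores (0.80 before, 0.41 after) and the call ended (camera adjusted p = 0.121), as it did with surrogate variables (0.46, camera adjusted p = 0.0526). A biological effect of diet and phlorizin on interferon signalling stays open.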

How the results depend on the processing

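The regional scores and the fits without doubted libraries were chosen after the data were seen, and the other alternatives before. Changing the scaling factors to RLE or upper quartile kept every count of genes within 1.5 times and shifted the median of all genes by less than 0.1, and filtering by CPM also kept every count within 1.5 times. The variance between groups was 59.0% over the most variable genes and 50.5% with the CPM filter. For single genes named in the text, the alternatives set beforehand kept the status, called or not called, in 2358 cases. They lost 71 calls, gained 4 and reversed 0, and 2 uncalled estimates took the other sign. Of the losses, 15 came with only the 12 libraries compared and 15 with surrogate variables. Most of these alternatives left out 1 library, and many of the genes were named for a small p in these data. Depth limits genes below 1 CPM, such as Slc5a2. Where a value moved, the cause was not tested, except that an added fold minimum by construction leaves fewer calls.

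Genes called between HFFD and Control, HFFD+HPH and HFFD, and HFFD+HPH and Control were 5810, 892 and 1212 with a 1.5-fold minimum, 1681, 628 and 1031 with surrogate variables, 5865, 210 and 1047 with the choroid plexus score, and 12, 24 and 200 with the 3 regional scores. The last 2 comparisons gave 763 and 1013 genes without a filter, and 68 and 188 with only the 12 libraries compared. DESeq2 called 2452 and limma-voom 7751 genes for HFFD+HPH against HFFD. Without the doubted libraries 22 genes (HFFD+HPH 3, 4 and 6 left out) and 35 genes (1, 2 and 5 left out) were called.

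Lists called were 7 and 6 with surrogate variables for HFFD against Control and HFFD+HPH against HFFD, and 0, 1 and 0 with an estimated correlation over the 3 comparisons. Between HFFD+HPH and HFFD they were 9 with the regional scores, 13 without the doubted libraries, 3 by directional fry and 0 by exact permutation. Between HFFD+HPH and Control they were 22 without a filter, 8 without the doubted libraries, 2 by fry and 0 by exact permutation. The smallest p that exact permutation can give is 0.00216, so that 1 list at that p alone cannot pass adjustment over 52 lists. The glucocorticoid scores of HFFD (-0.517 to -0.261) and HFFD+HPH (0.162 to 0.375) did not overlap.

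The correlation of both effects was -0.615 by DESeq2, -0.909 by limma-voom, -0.586 without a filter, -0.711 with surrogate variables and -0.534 with the regional scores. Opposite calls were 2199 by DESeq2, 6834 by limma-voom, 724 without a filter, 56 with only the libraries compared, 349 with surrogate variables, 183 with the choroid plexus score and 0 with the regional scores.

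Replicate numbers are shared between groups, but only 3 of 18 same-numbered pairs had deviations correlated over 0.1 (from -0.336 to 0.339), and 1 of 18 libraries correlated best with its own number. With the replicate number as a block, 225 genes were called for HFFD+HPH against HFFD, 1408 for HFFD+HPH against Control and 208 in opposite directions. With it, 21, 21 and 14 lists were called.

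Leaving out 1 library at a time gave 8392 to 9887 genes for HFFD against Control, 185 to 4362 for HFFD+HPH against HFFD, and 647 to 3925 for HFFD+HPH against Control. In HFFD+HPH against HFFD the count moved by over 1.5 times without HFFD 1 (813), 3 (413), 4 (363), 5 (256) or 6 (456), or HFFD+HPH 1 (2676), 3 (185), 4 (378), 5 (4362) or 6 (249). In HFFD+HPH against Control it did so without Control 1 (796), 2 (708) or 3 (1070), or HFFD+HPH 1 (647), 2 (951), 3 (3925), 4 (3588) or 5 (1220). Opposite calls ranged from 173 (without HFFD+HPH 3) to 3827 (without HFFD+HPH 5), and were 764, 388, 340, 238 and 421 without HFFD 1, 3, 4, 5 and 6, and 2547, 350 and 229 without HFFD+HPH 1, 4 and 6. Lists ranged from 20 to 25, 20 to 25 and 11 to 17, the correlation from -0.865 to -0.757, and the variance from 43.6% to 50.7%.

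Among named genes of HFFD+HPH against HFFD, the calls of Irf9, Ifit3, Hspa5, Creld2 and Slc2a1 were lost without HFFD 5 (-0.42, -0.62, -0.23, -0.35 and 0.42) or HFFD+HPH 3 (-0.58, -0.83, -0.25, -0.36 and 0.44). That of Ifit3 was also lost without HFFD 1 (-0.82). Without HFFD 3 or HFFD+HPH 4 those of Irf9 (-0.54, -0.52), Ifit3 (-0.77, -0.80) and Hspa5 (-0.25, -0.24) were lost. Without HFFD+HPH 6 those of Irf9 (-0.49), Ifit3 (-0.78), Hspa5 (-0.23) and Creld2 (-0.31), and without HFFD 4 or 6 those of Hspa5 (-0.23, -0.20) and Creld2 (-0.34, -0.29). Bdnf was called without HFFD+HPH 5 (0.45). Against Control, Arc was lost without Control 1 (-1.43) or 2 (-1.50) or HFFD+HPH 1 (-1.48), and Aldoa without Control 2 (-0.34).

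With the 3 regional scores, of 87 pairs of a named gene and a comparison 23 stayed as they were, 45 calls were lost and 17 took the other sign, and 2 uncalled estimates also changed sign. The log2 fold change between HFFD and Control took the other sign for Syn1 (0.14), Dlg4 (0.29), Gabra4 (0.52), Npy (0.086), Cck (0.17), Csf1r (0.57), Cx3cr1 (0.72), C1qc (0.63), Serping1 (-1.43), H2-D1 (-0.40), S100b (-0.14), Cd44 (-0.45), Otx2 (-0.16) and Aqp4 (-0.32). That between HFFD+HPH and Control did so for Syn1 (0.13), Aqp4 (-0.21) and S100b (-0.12).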

Other observations

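The genes of this part outside the rule for named genes, Plin4, Fmo2, Nrros and Gapdh, were chosen after their values were seen, and no test beyond those described was run for it.

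Among the 19 genes called between HFFD+HPH and HFFD in all 3 fits were several outside the lists. Plin4, which coats lipid droplets, stood at 32.1 ± 13 CPM in Control, 10.6 ± 4.60 in HFFD and 46.3 ± 13.7 in HFFD+HPH (mean ± SD, n = 6 each), a rise of 2.12 ± 0.31 with phlorizin (edgeR adjusted p = 0.00227). Fmo2, a flavin monooxygenase, stood at 3.75 ± 0.704, 3.00 ± 0.450 and 7.06 ± 2.04 CPM and rose by 1.23 ± 0.19 (edgeR adjusted p = 0.00365). Nrros, a myeloid gene that takes part in activating TGF-beta, stood at 6.47 ± 1.03, 4.34 ± 0.511 and 7.88 ± 0.972 CPM and rose by 0.86 ± 0.12 (edgeR adjusted p = 0.00207).

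Between HFFD and Control, of 13 reactive-astrocyte genes 4 rose and 1 fell by either adjustment (median 0.39, camera adjusted p = 0.0837), the hyaluronan receptor gene Cd44 from 2.61 ± 0.792 to 8.75 ± 2.32 CPM. Of 10 complement genes 5 fell and 1 rose, 5 and 2 when adjusted over the list alone (median -0.42, camera adjusted p = 0.379), C1qc from 25.4 ± 3.29 to 16.0 ± 2.86 CPM, while Serping1, the C1 inhibitor gene, rose from 5.04 ± 1.28 to 14.8 ± 3.34 CPM. Of 15 choroid plexus genes 2 rose, 0 when adjusted over the list alone (median 1.29, camera adjusted p = 0.0142, and adjusted p = 0.690 with an estimated correlation), among them Otx2, from 2.32 ± 3.74 to 10.9 ± 5.23 CPM. The choroid plexus score was 2.55 in Control 4 and -1.94 to -1.41 in the other Control libraries, and -1.11 and -0.63 in HFFD 1 and 2 and 1.63 to 2.75 in the other HFFD libraries. Between HFFD+HPH and HFFD the choroid plexus median was -1.37 (camera adjusted p = 0.0101, and adjusted p = 0.603 with an estimated correlation), and edgeR called 0 of its 15 genes (0 at an unadjusted p under 0.05, 0 by DESeq2, 1 by limma-voom).

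Gapdh, whose mRNA is abundant in brain and which has many processed pseudogenes, was counted at 25.1 ± 21.7 CPM in Control, 16.5 ± 2.67 in HFFD and 16.3 ± 0.694 in HFFD+HPH, with 69.2 CPM in Control 1. The ratio of Gabra6 to Cbln3 lay between 0.385 and 0.481 in all 12 HFFD and HFFD+HPH libraries, while Gabra6 itself ranged from 11 to 583 CPM.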
